A study of Homo sapiens with 7 samples.

How the data were processed

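Genomic DNA was measured from MV4-11 cells carrying the Bassik human CRISPR knockout library: 1 library at day 0, and 1 each in vehicle, 40 nM and 100 nM GSK3685032 at day 8 and at day 24. The deposited table holds read counts per guide: its values are whole numbers with a different total in each library, and no normalization is stated for them. The labels name bcl2fastq, cutadapt and Bowtie2 without versions; their parameters, filters and guide reference are not stated. A change in any of these would alter how many reads each guide received, and reads without molecular identifiers are not independent molecules. The table also holds 2 columns that match no sample of the series, and these were not used.

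Each guide's name gives a gene symbol and Ensembl identifier, or marks a safe-targeting or non-targeting control. Of 20651 genes, 18180 symbols were current in a RefSeq gene table (GRCh38.p14), 1427 matched through a synonym and 1044 had no match; names were kept as deposited. The genome build behind the guides is not given in the sources used here, so no coordinates are printed. There were 81 symbols shared by more than 1 Ensembl identifier, and such genes are named with their identifier. Guides that share a sequence with another numbered 9516, none with over 5 reads at day 0. Guides were 16 to 24 bases long. Of 6750 non-targeting guides, 2267 had under 10 reads at day 0.

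For each pair of libraries, counts were scaled to equal totals and a pseudocount of 5 was added. A guide entered when its 2 scaled counts summed to at least 50. The median log2 fold change of safe-targeting guides was set to 0, and each guide's value was divided by the SD of safe-targeting guides of like mean count (20 bins). A gene's score was the mean without its highest and lowest guide. It was compared with 1000000 random sets of as many safe-targeting guides (two-sided permutation test, smallest possible p 2e-06), with Benjamini-Hochberg adjustment over genes with at least 4 guides and a threshold of 0.05. The printed effect is the mean log2 fold change without the highest and lowest guide. The SE beside it is taken over all entered guides of the gene, the highest and lowest included. It is thus the SE of the untrimmed mean. Because each group has 1 library, this test compares the libraries, not the conditions; a difference between cultures from any cause would pass it. Safe-targeting guides were chosen as controls because they cut DNA as gene-targeting guides do. Centring on all gene-targeting guides instead would lower every value against DMSO at day 24 by 0.01 in 100 nM and 0.26 in 40 nM; with non-targeting guides the values in 100 nM would be lower by 0.43.

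The comparisons were each dose against DMSO at each day, 100 nM against 40 nM at day 24, and DMSO against day 0; drug libraries were also set against day 0. The difference of the drug effects of days 24 and 8 was tested in the same way. A dose-by-day trend over all 7 libraries was fitted with edgeR (quasi-likelihood test, day as a factor, TMM). There are 31 gene lists, fixed before the data were examined, among them cytosolic ribosome, proteasome, DNA replication, respiratory complex I, Mediator, cullins and neddylation, leukaemia dependencies, DNA methylation, H3K9 methylation and HUSH, PRC1, PRC2, H3K4 methylation, HDAC corepressors, histone acetyltransferases, BAF, apoptosis, interferon and double-stranded RNA, G1 cell cycle, RAS-MAPK, mTOR and GATOR, SUMO, base excision, Fanconi and recombination, ATR checkpoint, mismatch repair, methionine and SAM, nucleoside analogues, drug efflux, olfactory receptors and keratin-associated proteins. Each list's median was placed among 10000 random lists of equal size matched on count in 10 bins, which is a description and not a test across samples. Lists outside percentiles 2.5 to 97.5 are named as such.

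Genes were named by a rule set beforehand: up to 12 per direction with the largest change among those passing at day 24 in 100 nM, 8 at day 24 in 40 nM and in DMSO against day 0, and 4 elsewhere. Where fewer than 4 passed in a direction, the 3 with the smallest p were added. DNMT1 was named throughout, and the rule also took up to 4 members per list with the smallest p at day 24 in 100 nM, of which the text prints a part. Other named list members, and the genes passing at day 24 in 40 nM beyond the first 8, were chosen after their values were seen. Results that rest on some genes and on a list are not reported here; counts of genes past the threshold include all genes.

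The alternatives planned beforehand were a pseudocount of 1, a minimum sum of 1 or 200, non-targeting guides as controls, centring on gene-targeting guides, the median as gene score, a Mann-Whitney test, values not divided by the spread, a threshold of 0.10, and a growth correction from the compared libraries. For the trend they were DESeq2, no filter, dose as 0 or 1, and leaving out each library. Alternatives added after the data were seen were controls of like day 0 count, a growth correction from libraries outside the comparison, and a day 0 count of at least 50 as the filter. Guide names carry no sub-library, so centring by sub-library was not possible and all safe-targeting guides were used together. The test was checked on simulated data in which 80% of the guides of 200 genes were active. Among its calls, false ones made up 7.5% at day 24 in 100 nM, 7.8% in 40 nM and 3.6% at day 8 in 100 nM. The share was 2.7% in DMSO against day 0 and 17.6% (3 calls) in 100 nM against 40 nM. The simulated noise came from the same safe-targeting guides as the random sets. These shares therefore cannot show whether gene-targeting guides behave like them. The shares also depend on how many genes were changed, 200 in the simulation. They do not carry over to the 6 and 18 genes called at day 24 in 100 nM and 40 nM. Among olfactory receptors, the share with an unadjusted permutation p under 0.05 ranged from 3.7% (day 8 40 nM against day 0) to 14.6% (day 24 100 nM against day 0). Against DMSO at day 24 it was 11.1% in 100 nM and 7.4% in 40 nM.

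Library depth ranged from 64972042 to 113322330 reads. The median count of guides present at day 0 was 377 at day 0, 305 in DMSO, 282 in 40 nM and 275 in 100 nM at day 8, and 316, 189 and 73 at day 24. Intervals for shares are Wilson intervals at 95% and cover counting error only. Software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16 and DESeq2 1.42.0.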

Results

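The screen asked which gene knockouts change the growth of MV4-11 cells exposed to GSK3685032, an inhibitor of DNMT1, the enzyme that copies DNA methylation onto newly made strands. MV4-11 is an established acute myeloid leukaemia line driven by an MLL fusion. The cells carried a genome-wide knockout library of about 10 guides per gene, and genomic DNA was read at day 0 without treatment, and at days 8 and 24 in vehicle (DMSO), 40 nM or 100 nM compound. Each of these 7 conditions had 1 library, so no replicate cultures exist, and every standard error (SE) below is over the guides of a gene, not over cultures. The labels' source field names macrophage, which differs from the identity of the line that their other fields give.

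The library of day 0 held 87935266 reads. At day 8 there were 73021238 in DMSO, 66110563 in 40 nM and 64972042 in 100 nM, and at day 24 80086640, 113322330 and 88714173. The table held 218049 guides, of which 204549 targeted 20651 genes, 6750 cut genomic sites meant to be harmless (safe-targeting guides) and 6750 had no target. At day 0, 14255 guides (6.54%) had no reads. Of the guides present at day 0, 1.01% were lost by day 24 in DMSO (95% Wilson interval 0.963 to 1.05%), against 5.80% at 40 nM (5.70 to 5.91%) and 25.8% at 100 nM (25.61 to 25.99%). Such intervals and limits cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

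Guide representation narrowed in both day 24 drug libraries. At day 0, 54623 guides held 50% of the reads, and in DMSO at day 24 46144 did. The corresponding numbers were 10455 at 40 nM and 8634 at 100 nM. The Gini coefficient of the guide counts, which is 0 when all guides are equally abundant, was 0.355 at day 0, 0.428 in DMSO at day 24, 0.736 at 40 nM and 0.811 at 100 nM. Among safe-targeting guides, the standard deviation (SD) of the log2 fold change against DMSO was 2.70 at 100 nM and 1.98 at 40 nM on day 24, but 0.55 and 0.47 on day 8. Their median count at day 24 was 336 in DMSO, 173 at 40 nM and 77 at 100 nM. Since fold changes are centred on these guides, a guide can count as higher although its own reads fell. A guide with 0 reads in the day 24 100 nM library could have had up to 0.0338 reads per 1000000 reads (RPM).

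**Figure D1:**
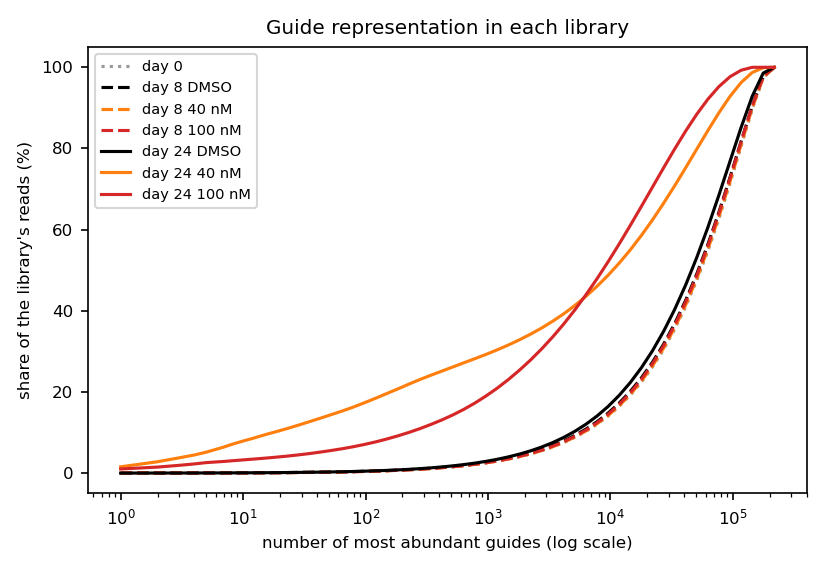
Cumulative share of each library's reads (y axis, percent) held by its most abundant guides (x axis, number of guides, log scale), one line per library. The 10 most abundant guides held 7.94% of reads in the day 24 40 nM library and 3.29% in the day 24 100 nM library, against 0.10% at day 0.

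Growth in vehicle was examined first, since it shows which genes MV4-11 cells need. From day 0 to day 24 in DMSO, guides against CCT5, a subunit of the cytosolic chaperonin, fell by 2.53 on the log2 scale (SE 0.48). Guides against SOD1, the cytosolic superoxide dismutase, fell by 2.28 (SE 0.50), and those against the ribosome recycling factor ABCE1 had a value of -2.17 (SE 0.49). Other falls were those of NEDD8, the ubiquitin-like modifier of cullins (-2.16, SE 0.52), the tyrosyl-tRNA synthetase YARS (-2.11, SE 0.46), the respiratory chain assembly factor COA7 (-2.37, SE 0.28) and the kinase SIK3 (-2.24, SE 0.39). The readthrough gene URGCP-MRPS24 fell by 2.14 (SE 0.84). In the opposite direction, guides against PTPN1, a tyrosine phosphatase, rose by 1.11 (SE 0.17) and those against the H3K4 methyltransferases KMT2C and KMT2D by 0.84 (SE 0.17) and 0.75 (SE 0.14). FAM98A (0.78, SE 0.17), UXS1 (0.75, SE 0.16), AKR1C1 (0.76, SE 0.23) and LMO4 (0.76, SE 0.20) also rose. DNMT1 itself fell by 0.77 (SE 0.28, lower with 8 of 10 guides, adjusted permutation p = 0.00758).

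Many of the fixed gene lists lost members in DMSO. Of 46 DNA replication genes 33 were lower by day 24 (median log2 fold change -0.99), as were 33 of 78 cytosolic ribosomal proteins (-0.71), 28 of 37 proteasome subunits (-0.89), 25 of 33 subunits and assembly factors of respiratory complex I (-1.15), 24 of 33 Mediator subunits (-0.83) and 18 of 22 cullin and neddylation genes (-1.03). Among genes on which MLL-rearranged leukaemia is known to depend, 30 of 41 were lower (-0.84). The Fanconi and homologous recombination list had 22 of 29 members lower (-0.98), and the ATR checkpoint list 13 of 22 (-0.76). The H3K4 methylation list (-0.95) had 13 of 21 members lower and 4 higher. Chromatin and signalling lists were lower as well, with 14 of 23 BAF and remodelling genes (-0.82), 21 of 36 histone acetyltransferase genes (-0.67; 1 higher), 13 of 30 HDAC corepressor genes (-0.42; 2 higher), 16 of 22 methionine and SAM genes (-0.76) and 15 of 31 mTOR and GATOR genes (-0.68). All lists named so far lay at percentile 0.02 or lower of random matched lists. H3K9 methylation (-0.54), SUMO (-0.73) and base excision repair (-0.36) also lay outside the middle 95%. Among olfactory receptors, which these cells are not known to need, 6 of 378 were lower and 1 higher, with a median of -0.13. Adjusted over the list alone, the lower genes numbered 42 for replication, 50 for the ribosome, 29 for the proteasome, 26 for complex I and 0 for the olfactory receptors.

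Over all 19680 genes tested, 2563 were lower and 71 higher from day 0 to day 24 in DMSO (two-sided permutation test against sets of safe-targeting guides, adjusted p under 0.05). At day 8 the counts were 2028 and 33 of 19695. With non-targeting guides as controls in place of safe-targeting ones, 6365 and 4891 genes passed at days 24 and 8, LMO4 and AKR1C1 no longer did, and PPP1CC no longer did at day 8. With a minimum of 200 scaled counts SOD1 had -1.40 and NEDD8 -1.35 at day 24, and both passed. Non-targeting guides, which make no cut, had a median of 0.23 against safe-targeting guides by day 24.

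Early loss in DMSO by day 8 was largest in absolute size for AC026407.1 (-1.71, SE 0.04), which had 4 guides, followed by the tRNA synthetases YARS (-1.25, SE 0.16) and NARS (-1.25, SE 0.14) and UROS (-1.21, SE 0.13), an enzyme of haem synthesis. CDC14B (0.47, SE 0.14), AKR1C1 (0.44, SE 0.17) and PPP1CC (0.42, SE 0.15) rose. DNMT1 had a value of -0.24 (SE 0.05) and did not pass, though it did with a Mann-Whitney test and with non-targeting controls. AKR1C1 lost its call at day 8 in most alternatives. The falls were shared with day 24 in 1696 genes, where 264.2 would be shared if the lists were independent; both comparisons use the day 0 library.

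At day 24 in 100 nM compound, guides against 6 genes rose against DMSO, and none fell. RNF4 (ENSG00000063978), a ubiquitin ligase that targets SUMO-modified proteins, rose by 9.85 on the log2 scale (SE 0.91, 8 of 8 guides past the minimum count, which a guide low in both libraries does not reach). Its guides together held 25.2 RPM in DMSO and 20920 at 100 nM, or 2.09% of the library. AHR (ENSG00000106546), the aryl hydrocarbon receptor, rose by 4.55 (SE 0.85, 9 of 10 guides), and its dimerisation partner ARNT (ENSG00000143437) by 3.76 (SE 0.95, 9 of 10 guides). The ARNT guides counted as higher include those that went from 1412 reads in DMSO to 612 at 100 nM and from 546 to 452.

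Among the genes that rose at day 24 in 100 nM compound were also NOA1 (ENSG00000084092), a GTPase of mitochondrial ribosome assembly, by 5.26 (SE 0.59, 9 of 9 guides), and PUS1 (ENSG00000177192), a pseudouridine synthase of tRNA in mitochondria and nucleus, by 4.09 (SE 0.78, 9 of 10 guides). Both had fallen in DMSO from day 0 to day 24, with values of -1.56 (SE 0.32) for NOA1 and -1.16 (SE 0.23) for PUS1. Of the 82215 ARNT reads at 100 nM, 68569 belonged to a single guide, and of the 104698 AHR reads, 67403 did. The trimmed mean used here sets the highest guide of each gene aside.

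Adjusted permutation p values were 0.0098 for RNF4, NOA1 and AHR, 0.0314 for PUS1 and 0.0327 for ARNT, over 19604 genes; unadjusted p was under 0.05 for 630 genes upward and 533 downward. NOA1 (0.0952) and ARNT (0.0706) no longer passed with the median of the guides as the gene score, ARNT (0.175) and PUS1 (0.0952) not with a Mann-Whitney test, and PUS1 not with a pseudocount of 1 (0.0653) or controls of like day 0 count (0.0833). With a growth correction fitted on the compared libraries, whose covariate contains the drug library, the values were 2.68 for RNF4, 3.27 for NOA1, 1.74 for AHR and 2.61 for PUS1, which passed, and 1.07 for ARNT, which did not (adjusted p 0.0557). On simulated data with this library's spread, 80% of genes raised by 5 on the log2 scale were recovered, 20.8% of those raised by 3 and 25% of those lowered by 3. Among olfactory receptors, 11.1% had an unadjusted permutation p under 0.05 in this comparison, more than the threshold would give without any difference.

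DNMT1 had a value of -1.35 (SE 0.78, higher with 3 of 9 guides) at day 24 in 100 nM against DMSO and did not pass (adjusted permutation p = 0.918). DNMT1 guides together held 39.5 RPM in DMSO and 7.98 at 100 nM. Those counted as higher include guides that went from 387 to 152 reads and from 529 to 155. UHRF1, its partner in maintenance methylation, was not analysed here, since no guide carried that symbol. The downward genes with the smallest p, none of which passed, were ALG9 (ENSG00000086848) with -3.26 (SE 0.34), the leukocyte receptor CD300A (-3.54, SE 0.78) and the lysosomal ceramidase ASAH1 (-3.40, SE 0.31). Across the 21 measured genes of DNA methylation the median was 0.52, at percentile 99.01 of random lists matched on count, with no member passing over all genes or adjusted over the list alone. That median became -0.002 (percentile 92.8) with a pseudocount of 1 and 0.12 (percentile 76.83) with a minimum of 200 scaled counts. Its members with the smallest p had values of 2.01 (SE 1.18) for CDCA7, -2.11 (SE 0.66) for the deubiquitinase USP7, 1.52 (SE 0.78) for the remodeller HELLS and 1.22 (SE 0.49) for the de novo methyltransferase DNMT3A.

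The kinase ATM had a value of 3.49 (SE 0.83) at day 24 in 100 nM compound, and the pore-forming apoptosis protein BAX one of 4.02 (SE 1.18). Neither passed over all genes, with an adjusted permutation p of 0.056 for ATM and 0.0642 for BAX. Both passed with undivided guide values, ATM also without a filter and with the outside growth correction, and BAX with controls of like day 0 count and with the growth correction from the compared libraries. Neither passed with the median of the guides or a Mann-Whitney test.

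Respiratory complex I genes had the highest list median at day 24 in 100 nM compound, 1.26 over 33 genes, above all random matched lists (percentile 100). None of them passed over all genes. Adjusted over the list alone 3 were higher, NDUFA1 (3.79, SE 0.75), NDUFC1 (3.37, SE 0.96) and NDUFB6 (2.91, SE 0.81). The list of BAF and other nucleosome remodellers had a median of 0.73 (percentile 99.96) with no member passing either way; SMARCD2 had a value of 2.37 (SE 0.68) and BRD7 of 2.88 (SE 1.02). Olfactory receptors had a median of -0.60 (percentile 0.41), which became 0.09 when safe-targeting guides of like day 0 count were set to 0.

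These further lists lay inside the middle 95% of random lists at day 24 in 100 nM compound. In the SUMO list (median 0.12) RNF4 alone passed, in the apoptosis list (0.25) BAX alone passed when adjusted over the list alone, and in the H3K9 methylation and HUSH silencing list (-0.16) SUV39H1 did so (2.47, SE 0.70). No member passed either way in the lists that follow. Their medians were -0.47 for the cytosolic ribosome, -0.14 for the proteasome, -0.35 for DNA replication, -0.16 for leukaemia dependencies, 0.12 for double-stranded RNA sensing and interferon, 0.19 for PRC2, 0.02 for PRC1 and 0.08 for H3K4 methylation. HDAC corepressors had -0.07, histone acetyltransferases -0.20, base excision repair -0.49, Fanconi and recombination -0.29, the ATR checkpoint -0.19, mismatch repair 0.22 and methionine and SAM metabolism -0.37. Nucleoside analogue handling had 0.02, drug efflux -0.39, mTOR and GATOR -0.04, RAS-MAPK 0.06, the G1 cell cycle -0.02, Mediator -0.22, cullins and neddylation -0.38 and keratin-associated proteins -0.14. The mean had the opposite sign to the median for PRC1 (-0.20), nucleoside analogue handling (-0.10) and drug efflux (0.02). The ribosome median became 0.31 with a minimum of 200 scaled counts and 0.11 with controls of like day 0 count. With non-targeting controls all medians at this dose and day are lower by 0.43, which turns those of apoptosis, double-stranded RNA sensing, PRC1, PRC2, H3K4 methylation, mismatch repair, nucleoside analogue handling, RAS-MAPK and SUMO negative. The median over all genes was -0.16 at day 24 in 100 nM and 0.21 in 40 nM.

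At day 24 in 40 nM compound, guides against 18 genes rose against DMSO, and none fell. RNF4 again had the highest value, 11.14 (SE 1.01, 9 of 9 guides), and its guides made up 4.76% of the library's reads (95% Wilson interval 4.75 to 4.76%). RAB7A, a GTPase of late endosomes, rose by 3.54 (SE 0.57, 9 of 9 guides). HELLS, the remodeller needed for DNA methylation at repeats, rose by 3.46 (SE 1.0, 8 of 10 guides), AHR by 2.97 (SE 0.46, 10 of 10) and the H3K9 methyltransferase SUV39H1 by 2.87 (SE 0.85, 10 of 10). GSE1, a corepressor subunit, rose by 3.09 (SE 0.80), the double-strand break nuclease MRE11A by 2.81 (SE 0.58), WDR18 by 2.95 (SE 0.90), the tRNA splicing subunit TSEN54 by 2.90 (SE 0.76) and AC004076.9 by 3.41 (SE 1.49).

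Other genes that rose at day 24 in 40 nM compound included PITRM1, RPP30, IDH3A, SLC2A1, SCAF4, CS and GTPBP6; IDH3A and CS encode enzymes of the citric acid cycle. NOA1 (2.33, SE 0.38), ARNT (2.04, SE 0.72), PUS1 (1.42, SE 0.64) and DNMT1 (0.89, SE 0.75) did not pass at this dose. The downward genes with the smallest p, not passing, were CCDC149 (-2.47, SE 0.71), the huntingtin gene HTT (-2.36, SE 0.51) and TRBV10-2 (-2.97, SE 0.80). Both doses shared 3 risen genes, RNF4 and AHR among them, where 0.00551 would be shared if the lists were independent, with the day 24 DMSO library common to both.

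Several lists with members lost in DMSO had positive medians at day 24 in 40 nM compound: 1.19 for complex I, 1.04 for H3K4 methylation, 0.87 for BAF, 0.86 for the proteasome, 0.84 for the ribosome, 0.81 for methionine and SAM metabolism, 0.82 for leukaemia dependencies and 0.70 for replication. Each of these lay above 99.9% of random lists or more, although no member of these 8 lists passed over all genes. The loss in DMSO and this rise share the day 24 DMSO library, on opposite sides. Over all genes their rank correlation was -0.395, and across random sets of safe-targeting guides it was already -0.243. Adjusted over the list alone, 5 complex I genes, 4 methionine and SAM genes, 3 proteasome genes, 3 ribosomal proteins, 2 H3K4 methylation genes, 2 leukaemia dependencies (MLLT1, 2.48, SE 0.51, and SPI1, 2.49, SE 0.61) and 1 replication gene (MCM4, 2.19, SE 0.54) were higher, and 0 BAF genes. The DNA methylation list had a median of 0.22 (percentile 53.5), with HELLS past the threshold over all genes and CDCA7, which recruits HELLS, adjusted over the list alone (2.26, SE 0.82).

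Over 19627 genes at day 24 in 40 nM, unadjusted permutation p was under 0.05 for 1399 upward and 263 downward. The count of 18 became 9 with the median of the guides as gene score, 8 with a Mann-Whitney test, 29 with non-targeting controls, and 8 after a growth correction fitted on libraries outside the comparison, chosen after the data were seen. Those tests no longer called AC004076.9, WDR18 and TSEN54 in any of the median, Mann-Whitney and outside growth settings, and GSE1 in the median and Mann-Whitney settings; HELLS had an adjusted Mann-Whitney p of 0.18. With the growth correction from the compared libraries the values were 3.30 for RNF4, 1.65 for AHR and 1.19 for HELLS, which passed, and 0.90 for GSE1, which did not (adjusted p 0.0705).

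**Figure D2:**
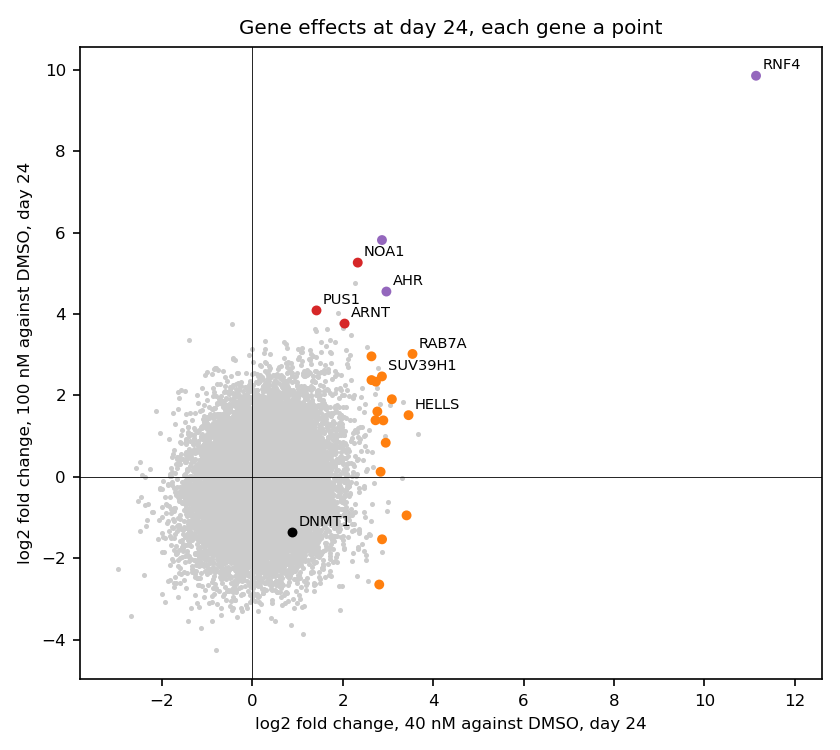
Log2 fold change against DMSO at day 24 in 100 nM (y axis) and in 40 nM compound (x axis), each point a gene; red, passing at 100 nM; orange, at 40 nM; purple, at both; black, DNMT1. RNF4 lies at 9.85 and 11.14, apart from all other genes, and DNMT1 at -1.35 and 0.89.

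The day 24 libraries at 100 nM and 40 nM were compared directly to ask about dose. No gene of 19369 passed (two-sided permutation test; unadjusted p under 0.05 for 325 upward and 886 downward). The upward genes with the smallest p had values of 3.45 (SE 1.19) for SHCBP1L, 3.67 (SE 0.88) for TRAV30 and 3.33 (SE 1.01) for FAM192A. Downward they were CITED2 (-5.63, SE 1.38), a transcriptional coregulator, MRE11A (-5.0, SE 0.41) and the CCAAT-binding subunit NFYB (-5.05, SE 1.10). NOA1 had 2.96 (SE 0.90) and DNMT1 -2.05 (SE 0.73). List medians were -1.53 for the ribosome (percentile 0), -1.29 for Fanconi and recombination (0.25), -1.31 for SUMO (1.03) and -0.99 for replication (1.52), against 0.15 for complex I (96.4). On simulated data with the spread of these libraries, 44% of genes raised by 5 on the log2 scale were recovered and 8.7% of those lowered by 5, so a count of 0 does not show that the doses acted alike.

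At day 8 in 100 nM compound, guides against 773 genes rose against DMSO and those against 14 fell. RNF4 rose by 1.35 (SE 0.28, 8 of 9 guides), and the proteasome subunit PSMD11 by 1.21 (SE 0.21). TRIM28, the corepressor that recruits H3K9 methylation, rose by 0.90 (SE 0.10), NOA1 by 0.60 (SE 0.10) and BAX by 0.53 (SE 0.11). CTB-60B18.6 (1.31, SE 0.44, 4 guides) and AC026369.1 (1.16, SE 0.20, 6 guides) also rose. The largest falls were those of TGFBRAP1 (-0.66, SE 0.21), PRG2 (-0.65, SE 0.28), the kinase BTK (-0.63, SE 0.24) and INSL6 (-0.62, SE 0.17); the dNTP hydrolase SAMHD1 fell by 0.51 (SE 0.14). DNMT1 had a value of 0.00 (SE 0.20) and did not pass.

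Several lists with members lost in DMSO had many that rose at day 8 in 100 nM. Of 33 complex I genes 21 rose over all genes and 25 adjusted over the list alone (median 0.56), with NDUFB11 at 0.86 (SE 0.17) and NDUFA1 at 0.85 (SE 0.26). The counts were 19 and 44 of 78 for the ribosome (0.47; RPL12 0.85, SE 0.28), 13 and 25 of 37 for the proteasome (0.46), and 14 and 27 of 46 for replication (0.40; GINS2 0.93, SE 0.21). Fanconi and recombination genes gave 7 and 15 of 29 (0.35; FANCA 0.74, SE 0.21), and leukaemia dependencies 7 and 15 of 41 (0.29), among them the FLT3 receptor (0.57, SE 0.16), MYC (0.69, SE 0.21) and CDK6 (0.63, SE 0.14). Of the 31 lists, 17 lay outside the middle 95% of random lists. Olfactory receptors, with a median of 0.05, or -0.04 when centred on gene-targeting guides, lay at percentile 0.

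Of the 773 genes that rose at day 8 in 100 nM, 612 had fallen in DMSO by day 24, where 100.7 would be expected if the lists were independent; these comparisons share no library. Across 19670 genes the rank correlation of the pair of effects was -0.441, and across random sets of safe-targeting guides it was -0.200. The effects are thus related without any gene effect, and the number under independence is too low a reference. Genes are not independent replicates. After the outside growth correction, chosen after the data were seen, 15 genes passed in place of 787, among them RNF4 (1.10), PSMD11 (0.81), TRIM28 (0.69) and BTK (-0.64). The count was 448 with the median of the guides and 1653 with non-targeting controls, and CTB-60B18.6, AC026369.1, TGFBRAP1, PRG2 and INSL6 each lost their call in at least 1 alternative.

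**Figure D3:**
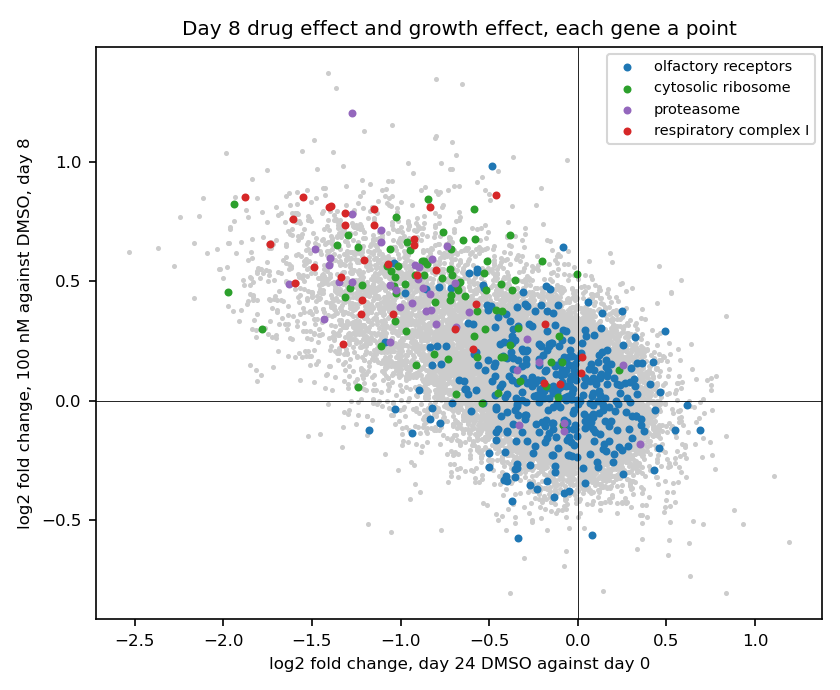
Log2 fold change of 100 nM against DMSO at day 8 (y axis) and of DMSO at day 24 against day 0 (x axis), each point a gene, with 4 gene lists in colour. Complex I, proteasome and ribosome genes, with y medians of 0.56, 0.46 and 0.47, lie mostly to the upper left, and olfactory receptors (0.05) near the origin.

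At day 8 in 40 nM compound, 1519 genes rose and 15 fell, of 19696. RNF4 rose by 1.28 (SE 0.08, 9 of 9 guides), BAX by 0.71 (SE 0.15), TRIM28 by 0.91 (SE 0.14) and HELLS by 0.39 (SE 0.13). The largest rises were those of AC026407.1 (1.73, SE 0.33), CTD-2410N18.5 (1.68, SE 0.41) and RP11-295P9.3 (1.35, SE 1.08), with 4 guides each, and RP11-1102P16.1 (1.32, SE 0.11, 9 guides). RASGEF1B (-0.48, SE 0.16), the melanocortin receptor gene MC4R (-0.47, SE 0.23), AKR1E2 (-0.45, SE 0.17) and FAM98A (-0.43, SE 0.15) fell. DNMT1 had a value of 0.11 (SE 0.09) and did not pass.

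Ribosomal proteins rose in 51 of 78 at day 8 in 40 nM over all genes and 67 adjusted over the list alone (median 0.58), complex I genes in 23 and 27 of 33 (0.58), proteasome subunits in 24 and 28 of 37 (0.53), replication genes in 19 and 29 of 46 (0.43) and leukaemia dependencies in 18 and 26 of 41 (0.40). The last included MEN1 (0.87, SE 0.21), MYB (0.76, SE 0.14), CEBPA (0.77, SE 0.19) and SPI1 (0.78, SE 0.08). Both doses shared 552 risen genes at day 8, against 59.46 if independent, with the DMSO library in common. Of the 1516 risen genes also measured at day 24, 1037 had fallen in DMSO, against 197.5 if independent. That reference is too low as well, since safe-targeting guide sets had a rank correlation of -0.202 between these effects. The count of 1534 became 53 after the outside growth correction, 975 with the median of the guides and 3773 with non-targeting controls; RASGEF1B, MC4R, FAM98A, AC026407.1, CTD-2410N18.5 and RP11-295P9.3 each lost their call in at least 1 alternative.

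How far each library reported on growth was measured by the area under the ROC curve, with 115 ribosome and proteasome genes against 465 to 468 olfactory receptor and keratin-associated genes; it is 1 when all ribosome and proteasome genes are the more depleted, and 0.5 when the sets are mixed. Against day 0 it was 0.835 in DMSO at day 8 (95% interval 0.794 to 0.879) and 0.893 at day 24 (0.855 to 0.929). The intervals of these areas come from resampling genes within each library and do not cover differences between cultures. In 40 nM compound it was 0.238 at day 8 (0.191 to 0.296) and 0.394 at day 24 (0.339 to 0.451), so that these ribosome and proteasome genes were the less depleted. In 100 nM it was 0.347 at day 8 (0.294 to 0.402) and 0.6 at day 24 (0.543 to 0.656). Against day 0, ribosomal proteins had a median of 0.26 in 40 nM at day 8, with 9 higher over all genes and 32 adjusted over the list alone, while the proteasome had 0.05 (percentile 80.11). Other lists with members lost in DMSO differed there. Complex I had 0.004 (percentile 39.22), leukaemia dependencies 0.04 (80.69) and SUMO 0.02 (52.34), while cullins and neddylation had -0.17 (percentile 0), Fanconi and recombination -0.16 (0), Mediator -0.09 (0.04) and replication -0.07 (0.03). Replication had -0.46 (0.09) and cullins and neddylation -0.59 (0.07) at day 24 in 40 nM against day 0, both below the olfactory receptors (-0.32). In 100 nM at day 8 the ribosome had 0.14 (percentile 100), with 0 genes higher over all genes and 4 adjusted over the list alone.

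Set against day 0 in place of DMSO, 4 genes rose at day 24 in 40 nM, among them RNF4 (10.26), HELLS (3.10) and SUV39H1 (2.81), and none fell. Of those that rose against DMSO at this dose, GSE1 (3.01, SE 0.77), AHR (2.35, SE 0.56), AC004076.9 (2.06, SE 1.09), WDR18 (1.43, SE 0.70), RAB7A (1.32, SE 0.42) and TSEN54 (1.26, SE 0.44) did not pass against day 0. In 100 nM, 6 rose, among them RNF4 (8.87), AHR (4.08), ARNT (3.79), ATM (3.62) and NOA1 (3.55), but not PUS1 (2.86, SE 0.70, adjusted p 0.1975), and 3 fell, the complex II subunit SDHA (-3.70, SE 0.42), ALG9 (ENSG00000086848) (-3.72, SE 0.38) and the histone chaperone SSRP1 (-3.64, SE 0.48); SDHA and SSRP1 lie outside the naming rule and were chosen after their values were seen. Replication genes (median -1.33), methionine and SAM genes (-1.41) and the ribosome (-1.18) lay at percentile 0 in 100 nM against day 0, and complex I (0.33) at 99.75. At day 8, 67 genes were higher and 91 lower in 40 nM against day 0, and 6 and 24 in 100 nM.

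**Figure D4:**
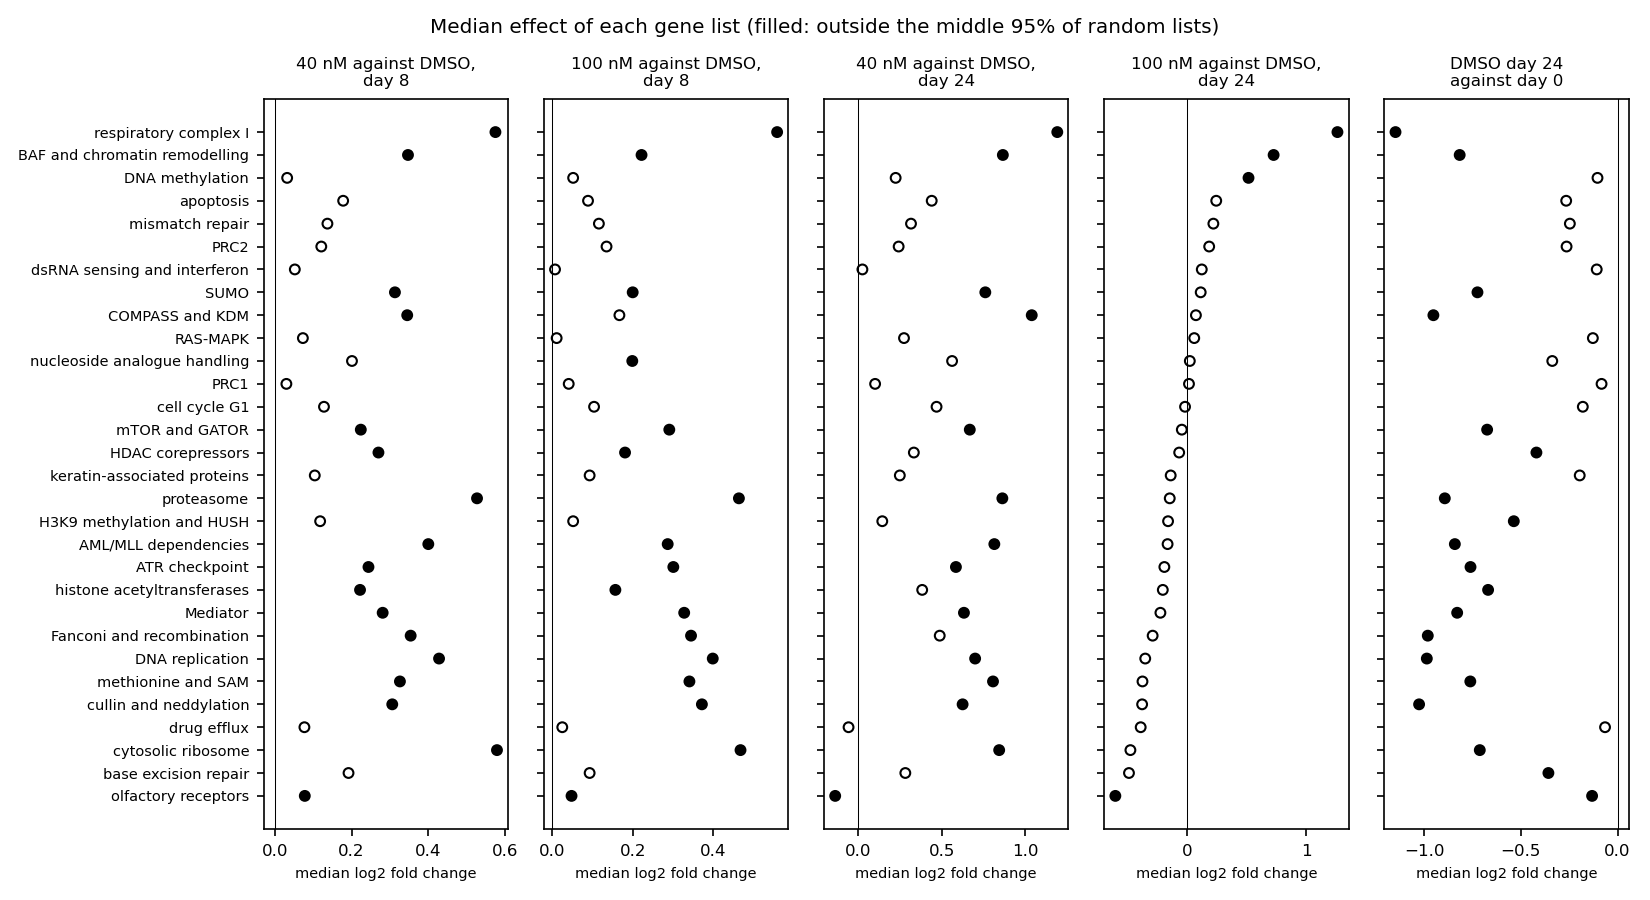
Median log2 fold change of each gene list named here (x axis of each panel) in 5 comparisons; filled points lie outside the middle 95% of 10000 random lists matched on count. Complex I has medians of 0.58, 0.56, 1.19 and 1.26 in the 4 drug comparisons and -1.15 in DMSO from day 0 to day 24. The day 24 drug comparisons share the day 24 DMSO library with the last panel, on opposite sides.

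The change of the 100 nM effect between days 8 and 24 was tested directly on 19587 genes. It rose for 6 genes, among them RNF4 by 8.60 (SE 1.0), NOA1 by 4.76 (SE 0.55), AHR by 4.49 (SE 0.80), PUS1 by 4.07 (SE 0.78) and ARNT by 3.58 (SE 0.93), and fell for no gene. Downward, HGFAC (-3.89, SE 0.39), CD300A (-3.46, SE 0.78) and AL138847.1 (-3.71, SE 0.51) had the smallest p and did not pass. DNMT1 had a value of -1.31 (SE 0.63). In 40 nM compound the same test found RNF4 alone (9.91, SE 1.0).

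A trend proportional to dose and day was fitted over all 7 libraries with edgeR, on reads summed per gene, which leaves 3 residual degrees of freedom. No gene of 20382 passed, with an unadjusted p under 0.05 for 5698. DESeq2 called 4258, 2178 upward and 2080 downward, and edgeR called 10844 without the day 24 40 nM library, though 0 without each other library. The smallest edgeR p upward belonged to the mitochondrial histidyl-tRNA synthetase HARS2 (2.68), AZIN1 (3.44) and LRPPRC (2.37), a mitochondrial mRNA-binding protein, and downward to IL13RA1 (-2.73), METTL25 (-2.74) and the deacetylase HDAC2 (-2.07), each with an adjusted p of 0.115. On simulated data a slope of -4 was recovered in 72% of genes and a slope of 4 in 16%.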

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

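The test of the difference between days was planned, and that of the CYP1 genes was set before their values were seen; all other tests in this part were chosen after the results they bear on were seen. Among the genes reported here, the drug effect at day 24 differed from that at day 8 for 6 results, by a permutation test of the difference itself, on the log2 scale. In 100 nM compound these were RNF4 (8.60), NOA1 (4.76), AHR (4.49), PUS1 (4.07) and ARNT (3.58), and in 40 nM compound RNF4 (9.91).

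The first pattern is the rise, at day 8, of genes that growth in DMSO requires. Drift of the DMSO culture alone would give the genes no larger a covariance with day 24 growth than safe-targeting guide sets have, yet it was 6.7 times as large (-0.047 against -0.007); this criterion was set with both values known. Slower loss of such knockouts in the drug culture is consistent with the rank correlation of -0.441 over all genes, against -0.200 in guide sets without a gene effect. Slower loss alone returns a knockout at most to its day 0 share. At day 8 the cytosolic ribosome list lay above day 0, with a median of 0.26 (95% interval over genes 0.212 to 0.344) in 40 nM. In 100 nM it was 0.14 (0.10 to 0.186), and 9 and 0 of its genes passed alone at these doses. For this list and these libraries only, the medians argue against slower loss as the whole cause. The intervals treat its genes as independent, and both doses share the single day 0 library, so an error there would move both. The list was chosen with its values known, and complex I and replication genes lay near or below day 0 in 40 nM at day 8. For the other genes a slower growth of all cells in drug and a lesser need for these genes may both give this relation, which was not separated here, and no replicate culture bears on it.

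The second pattern is the rise of RNF4 at both doses and both days. Expansion of a few chance clones would raise a minority of guides, but of the 9 RNF4 guides with at least 50 reads at day 0, 8 lay above the 99th percentile of safe-targeting guides at day 24 in 100 nM, and 8 in 40 nM. Among the 8 risen guides, 0 pairs shared their last 12 bases. Guides placed at different sites of a gene would differ there anyway, so this count cannot decide about off-target cutting. Cutting at different positions of a related sequence was not examined. An accident of a single culture would leave RNF4 near its day 0 level in the culture of the other dose. Against day 0, without the DMSO library, RNF4 rose by 8.87 (SE 1.40) in 100 nM and by 10.26 (SE 1.16) in 40 nM. This outcome was partly fixed in advance, since the pattern was chosen for its rise at both doses. Both values use the single day 0 library, and a cause common to both drug cultures stays open. A candidate explanation is that loss of RNF4 protects the cells from this compound, a hypothesis found and tested on the same libraries, without a replicate culture of either dose.

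The third pattern is the rise of AHR together with ARNT at day 24 in 100 nM. Slower loss of required genes could return at most what DMSO had taken, and the rise exceeded that whole loss by 3.55 for ARNT and 4.01 for AHR on the log2 scale; under the criterion first written, on the size of the loss alone (AHR -0.55, SE 0.28; ARNT -0.21, SE 0.36), the question stayed open, and this one was added with the values known. Inactivation of the compound by an AHR-induced CYP1 enzyme would make loss of AHR, ARNT or that enzyme more harmful, which lowers their guides. The rises of AHR (4.55) and ARNT (3.76) at day 24 in 100 nM go the other way. The test set beforehand took a CYP1 rise as its sign, so it does not bear on inactivation. It asks only whether loss of a CYP1 gene raised guides as loss of AHR and ARNT did. The highest value among CYP1A1, CYP1A2 and CYP1B1 was 0.42 (SE 0.65, CYP1B1), and CYP1A1 had 0.07 (SE 0.93). The permutation p adjusted over the 3 genes was 0.961 for each. Each value lay below the bound of 1.9, set beforehand from the value of ARNT, by more than its SE. A rise as large as that of ARNT was thus not seen, but a smaller one stays open. The p values cannot decide it, since simulated rises of 2 were recovered in 0% of genes here and rises of 3 in 20.8%. Redundancy among the 3 enzymes could also hide a rise, since each knockout was single. Chance clones cannot be told apart from an effect for ARNT, since 7 of 10 ARNT guides passed the 75th percentile of safe-targeting guides in 100 nM but 5 of 10 in 40 nM, against 9 of 10 AHR guides at both doses.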

How the results depend on the processing

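Controls of like day 0 count, the growth correction from libraries outside the comparison and the day 0 filter were chosen after the data were seen; the other alternatives were planned. Of the values of named genes under all alternatives, 2210 kept their direction and side of the threshold, 64 no longer passed, 37 newly passed, 54 moved and 2 reversed. The 2 were HDAC8 (1.46) and AHCY (1.77) at day 24 in 100 nM, under the growth correction from the compared libraries, whose covariate contains the drug library itself. The 2210 include values of genes that passed in neither setting, such as nearly all list members named at day 24 in 100 nM. The 64 can come only from genes that passed at first, so the total of 2210 does not measure how stable the calls are.

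At day 24 in 100 nM the count of 6 genes became 11 with undivided guide values, 11 at the threshold of 0.10 and 1292 with the growth correction from the compared libraries. At day 24 in 40 nM the count of 18 became 29 with non-targeting controls, 9 with the median score, 8 with the Mann-Whitney test, 1884 with the growth correction from the compared libraries and 8 with that from outside libraries. At day 8 in 100 nM the count of 787 became 1653 with non-targeting controls, 448 with the median score, 1197 at 0.10 and 15 with the outside growth correction, and in 40 nM 1534 became 3773, 975 (median score) and 53 (outside growth correction). With non-targeting controls the DMSO counts of 2634 (day 24) and 2061 (day 8) became 6365 and 4891. Lists outside the middle 95% at day 24 in 100 nM went from 4 to 8 with the minimum of 200 and to 19 with the growth correction from the compared libraries, and at day 8 in 100 nM from 17 to 7 with the outside growth correction. For the trend, edgeR's 0 became 4258 with DESeq2, and leaving out each library gave 0 to 10844, the highest without day 24 40 nM. For the changes in these counts, the cause was not tested, except that the threshold of 0.10 admits more genes by construction.

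The count between the doses at day 24 was 0 under all alternatives run, and the ROC areas moved by less than their 95% intervals without a filter or with a pseudocount of 1. The count of 6 genes whose 100 nM effect differed between days was 4 to 7, and NOA1 was lost from it with the median score. Centring on all control guides together equals the setting used, since the guide names give no sub-library, and so gives no separate value. No paired analysis was possible because each group has 1 library. Against DMSO at day 24, where the SD between safe-targeting guides was 2.70 in 100 nM and 1.98 in 40 nM, simulated changes of 2 on the log2 scale were recovered in 0 to 16.0% of genes. Read totals do not account for this, since both libraries (88714173 and 113322330 reads) were deeper than DMSO (80086640). The typical guide had fewer reads, however, with medians of 73 in 100 nM and 189 in 40 nM against 316 in DMSO. Whether this lowered the recovery was not tested.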

Other observations

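The tests and lists in this part were chosen after the data were seen. Genes of the mitochondrial ribosome (74 genes) and of mitochondrial tRNA charging (17 genes) were not among the lists fixed beforehand. In DMSO from day 0 to day 24, 68 of the 74 and all 17 fell, with medians of -1.09 and -1.26. The day 24 DMSO library also enters the drug effects of day 24 against DMSO, on the opposite side. At day 8 the mitochondrial ribosome had a median of 0.48 in 100 nM against DMSO, with 37 genes passing, and 0.47 in 40 nM, with 43. At day 24 in 40 nM the medians were 1.11 for the ribosome and 1.24 for tRNA charging, each at percentile 100 of matched random lists, with no gene passing. At day 24 in 100 nM they were 0.20 (percentile 98.65; negative with non-targeting controls, which lower it by 0.43) and -0.08 (52.57), beside 1.26 for complex I. Against day 0 the mitochondrial ribosome had -0.89 in 100 nM (percentile 0), where complex I had 0.33 (99.75).

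Safe-targeting guides, which cut the genome outside genes, can be set against non-targeting guides, which do not cut. The intervals of this comparison come from resampling guides within libraries and do not cover differences between cultures. Within bins of like day 0 count, non-targeting guides exceeded safe-targeting guides by 0.24 on the log2 scale in DMSO from day 0 to day 24 (95% interval 0.20 to 0.26), and by 0.13 to day 8 (0.10 to 0.15). In the drug libraries at day 8 the difference from day 0 was 0.04 in 40 nM (0.02 to 0.06) and 0.05 in 100 nM (0.02 to 0.07). At day 24 it was -0.03 in 40 nM (-0.13 to 0.07) and 0.22 in 100 nM (0.07 to 0.38). Against DMSO of the same day the differences were -0.09 in both day 8 drug libraries, -0.22 in 40 nM and 0.03 (-0.14 to 0.17) in 100 nM at day 24.

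The day 24 effects of the 2 doses were only weakly related across genes (Pearson r = 0.151 over 19587 genes, against 0.102 across random sets of safe-targeting guides, with the DMSO library in common). At day 8 the corresponding values were 0.667 and 0.436. The 40 nM effects of days 8 and 24, which share no library, had r = 0.384 against 0.246, and 14 of the 18 genes risen at day 24 had risen at day 8, where 1.39 would be shared if the lists were independent. For 100 nM r was 0.094 against 0.104, and 3 of 6 genes were shared (RNF4 and NOA1 among them), where 0.236 would be. The numbers under independence are too low a reference for both doses, since the effects are related across safe-targeting guide sets too.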
